A study of Homo sapiens with 5 samples.

How the data were processed

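RNA from 5 HMLE-derived cell lines was hybridised to Affymetrix arrays, 1 array per line, per the labels. The lines were the LACZ control and the FOXQ1, SNAI1, TWIST1 and ZEB2 lines, grouped by the sample labels. The submitters' processing notes name the Transcriptome Analysis Console and the genome build hg38; the version, settings, array model and normalization method were not given in the sources used here. The authors deposited 1 table of probe set values, read here as log2 values from their range of 1.99 to 19.73 with 2 decimals, since the base is not stated. Values above 16 exceed the log2 of a 16-bit scanner reading, so the scale had been transformed, and fold values hold only if the base is 2. Genes were not centred, since all values were above 0. Array medians between 4 and 4.05 show that the arrays had been brought to one scale by the authors. No centring or rescaling was added for the main values.

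The table held 65521 probe sets, with identifiers on chromosomes 1 to 8 and part of 9, and the rest of the genome was not analysed here. That includes the genes SNAI1, CDH1, VIM, CDH2, ZEB1 and OVOL1 and the keratins and metallothioneins. A platform annotation gave 16126 probe sets 1 gene symbol, 419 several and 48976 none. Symbols were matched to RefSeq genes of GRCh38.p14, in which 15764 probe sets were found, and 194 were left out because the chromosome in the identifier differed. This left 15570 probe sets of 14916 genes, of which 7794 were protein-coding. Each gene took the probe set with the highest mean over the 5 arrays. No detection calls were used, so signal over background was judged only by a level floor of 4.72, the median of gene mean levels, which 8495 genes reached on any array.

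A gene was called higher or lower on a factor array when it differed from LACZ by at least 2-fold, a log2 difference of 1, and the brighter of the pair was at or above the floor. Shared genes were called in the same direction on all 4 factor arrays. A gene set 1 factor array apart when it was called against LACZ, with the floor. It also had to differ by at least 2-fold, in that direction, from each other factor array, without a floor. The number of arrays limits the precision: with 1 per line there is no estimate of replicate error, and no test between lines and no p-value was computed. Calls against the shared LACZ array were set beside 100 simulated sets of 5 arrays without differences. Their noise was drawn from the TWIST1 and ZEB2 pair, which also holds real differences. Overlaps of independent lists and counts with each other array in the place of LACZ were also computed.

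Of 46 gene lists written before the data were examined, 2 had no measured member and 43 had at least 3. All 43 were computed on all 4 arrays, and the text gives those chosen with their values in view. The median of each was ranked among 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays. Named genes followed a rule written before the data were examined. It took the overexpressed factors, and in each direction the 12 shared genes with the largest smallest difference, the 10 genes with the largest difference per factor and the 5 that stood furthest apart from all 4 other arrays. It added members of the lists as examples and a fixed set of EMT genes. TERT and the genes of opposite direction in the closing section were chosen after their values were seen, apart from those the rule also names.

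The calling of shared genes was tested on simulated data with 14916 genes, of which 200 were changed. It recovered 15 of 67 genes changed 2-fold (22.4%), 55 of 67 changed 4-fold (82.1%) and 66 of 66 changed 8-fold (100%). The changed genes were drawn only from genes well above the floor on LACZ. Recovery of genes low or absent there, such as RGS4 and NID1, was not tested. Of 14716 unchanged genes 150 were called, and 0 changed genes were called in the wrong direction. Alternatives planned before the data were examined were quantile normalization, centring on the median gene, no floor or a floor at percentile 75, thresholds of 3-fold and 1.5-fold, the median of a gene's probe sets, and other definitions of sharing. Level-dependent normalization, a loess of each array against the mean array with a span of 0.3, was added after seeing the data, as were the counts without the SNAI1 and FOXQ1 arrays and the windows of 10 Mb along chromosomes. Windows needed at least 15 genes at or above the floor, and no other width was tried. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, with fixed seeds.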

Results

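Gene expression was measured on 5 Affymetrix arrays, 1 for each of 5 cell lines derived from HMLE, an immortalised line of human mammary epithelial cells. The control line carried LACZ, a bacterial reporter gene, and the other 4 lines overexpressed FOXQ1, SNAI1, TWIST1 or ZEB2, transcription factors known to drive the epithelial to mesenchymal transition (EMT). In EMT, epithelial cells lose their contacts and take on features of mesenchymal cells. The question of the study was which genes the 4 EMT models had in common and where they differed. Each line was represented by 1 array, so no difference had a replicate check, no test was possible and no p-values are given. Levels are on the deposited scale, read as log2, and every difference is a factor array minus the LACZ array on that scale. The values covered probe sets on chromosomes 1 to 8 and part of chromosome 9, in which 14916 genes were named. The median over all 65521 probe sets was 4.05 on the LACZ array, 4.03 on FOXQ1, 4.04 on SNAI1, 4 on TWIST1 and 4.03 on ZEB2. Genes at the bottom of the scale had no measured order, so large differences with one side there are not exact ratios. How the unstated transformation of the scale changed them is not known.

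The overexpressed factors were examined first. FOXQ1 (GRCh38.p14 chromosome 6, 1312098 to 1314758) had a level of 6.23 on its own array and between 3.56 and 3.61 on the other 4 arrays. TWIST1 (chromosome 7, 19113047 to 19117636) had its highest level, 9.96, on the TWIST1 array, against 5.55 on LACZ. It was also higher than LACZ on the arrays of the other factors, at 8.2 on FOXQ1, 9.18 on SNAI1 and 8.55 on ZEB2. ZEB2 (chromosome 2, 144384081 to 144520119) reached 7.39 on the ZEB2 array and 3.57 on LACZ, with 6.85 on FOXQ1, 6.23 on SNAI1 and 7.03 on TWIST1. Whether the probes of these genes lie in the part carried by each overexpression construct was not known here. The SNAI1 gene was not analysed here, so the label of its array had no such check.

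On all 4 factor arrays, 6 of 9 measured adherens and tight junction genes were lower and 5 of 9 collagen and matrix genes higher than on LACZ. MAL2, a membrane protein of apical transport in epithelial cells, had a level of 17.39 on LACZ and between 3.87 and 4.61 on the factor arrays. EPCAM, the epithelial cell adhesion molecule, was at 14.85 on LACZ and between 2.63 and 3.18 elsewhere. ESRP1, an epithelial regulator of splicing, was at 14.22 on LACZ and between 3.06 and 3.53 elsewhere. In the opposite direction, RGS4, a regulator of G protein signalling, was at 3.75 on LACZ and between 12.62 and 13.89 on the factor arrays, and NID1, a basement membrane glycoprotein, was at 3.19 and between 11.96 and 13.84.

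In all, 324 genes were 2-fold or more higher and 341 were 2-fold or more lower than LACZ on all 4 factor arrays. After RGS4 (chromosome 1, 163068871 to 163076802) and NID1 (chromosome 1, 235975830 to 236065090), the shared higher genes with the largest smallest difference were ABI3BP, NREP, BIN1, CADM3, DOCK10, CDH18, PLPP3, AK5, CITED2 and CPA4. CADM3, a cell adhesion molecule, differed by 5.76 on FOXQ1 and by 9.48, 9.67 and 9.99 on SNAI1, TWIST1 and ZEB2. CDH18, a member of the cadherin family, differed by 5.18, 7.85, 7.52 and 8.26 in the same order. CITED2, a transcriptional coregulator, differed by 5.63, 5.64, 6.13 and 5.06.

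After MAL2 (chromosome 8, 119208363 to 119245673), EPCAM (chromosome 2, 47369311 to 47387020) and ESRP1 (chromosome 8, 94641174 to 94707466), the shared lower genes led by the same measure were S100A14, IL1A, RAB25, IL1B, FAM83B, MACC1, HOOK1, FGFBP1 and OCLNP1. RAB25, a small GTPase of epithelial vesicle recycling, was at 12.39 on LACZ and between 3.24 and 3.73 on the factor arrays. The interleukins IL1A and IL1B, inflammatory cytokines, were at 15.17 and 15.43 on LACZ, and their smallest differences over the 4 arrays were -8.68 and -8.31. OCLNP1 is a pseudogene of the tight junction gene OCLN, and its signal may not be separable from that of OCLN. ESRP1, MAL2 and GRHL2 lie on the long arm of chromosome 8, where the 10 Mb windows that hold them had median differences, over the mean of the 4 arrays, of -0.25, -0.12 and -0.22. The probe sets of DOCK10 and MACC1 did not move alike: with the median of a gene's probe sets, DOCK10 differed by 3.67, 5.3, 3.96 and 4.42 and MACC1 by -4.12, -4.26, -4.35 and -4.51 on FOXQ1, SNAI1, TWIST1 and ZEB2.

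**Figure D1:**
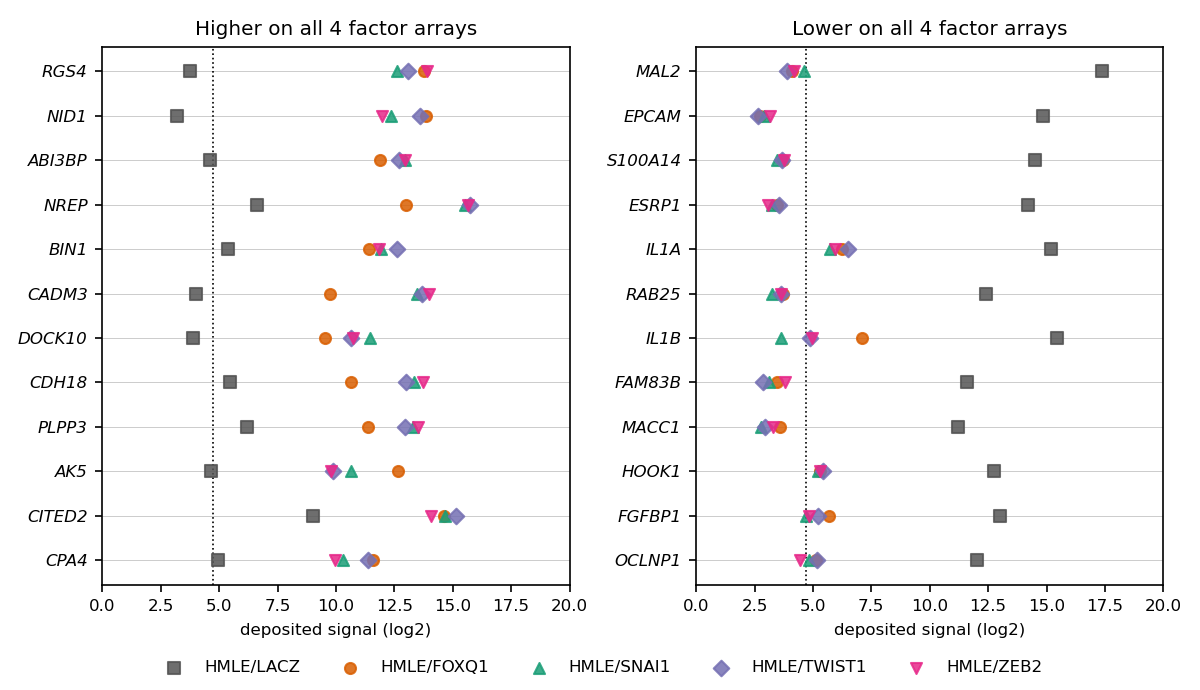
Deposited signal (log2, horizontal axis) of the 12 leading shared higher genes (left) and the 12 leading shared lower genes (right), 1 point per array, with the dotted line at the level floor of 4.72. EPCAM lies at 14.85 on LACZ and at most at 3.18 on the factor arrays, and RGS4 at 3.75 on LACZ and at least at 12.62.

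All 4 differences used the same LACZ array, which alone makes calls coincide. With 5 simulated arrays that differed only by noise, an average of 64.72 genes (at most 82 in 100 sets) were called higher on all 4. An average of 74.63 (at most 94) were called lower. The same arrays gave averages of 366.36 genes higher and 365.34 lower per array, so part of each single-factor count below may be noise. Independent lists of the observed sizes, drawn from all 14916 named genes, would share 0.19 and 0.15 genes. Lists drawn only from the 8495 genes that reached the floor on any array would share more. With each factor array put in the place of LACZ, the other 4 arrays lay on one side of it for fewer genes than the 665 of LACZ. The counts were 406 (FOXQ1), 225 (SNAI1), 63 (TWIST1) and 114 (ZEB2), with the floor applied to every pair. The counts of genes apart given below applied the floor only to the pair with LACZ. The differences correlated across genes with r between 0.653 (FOXQ1 and ZEB2) and 0.828 (TWIST1 and ZEB2), against 0.501 in the simulation; genes are not independent replicates. The covariance exceeded the simulated 0.137 by between 0.447 and 0.545. The single control array could not be split, so part of the excess may come from it.

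Among the gene lists fixed before the data were examined, the epithelial junction genes were lower on every factor array. Of 9 measured adherens and tight junction genes, 6 were 2-fold or more lower on all 4 arrays and none was higher, with list medians of -4.56 on FOXQ1, -4.82 on SNAI1, -4.41 on TWIST1 and -4.92 on ZEB2. All 4 medians lay at percentile 0 of 10000 random lists of the same size and level, a description of these arrays and not a test. CLDN1, a tight junction claudin, differed by -7.05, -9.23, -6.47 and -4.92, and OCLN, the tight junction protein occludin, by -6.56, -7.73, -6.74 and -6.75. CLDN3, counted among the 9, was below the floor on all 5 arrays, so its difference is uncertain although it enters the medians. With the median of all probe sets of a gene, the list medians were -3.04, -3.87, -2.9 and -2.78. Of 3 measured desmosome genes, DSP, the plaque protein desmoplakin, differed by -4.09, -2.74, -3.05 and -2.72, while PKP1 was 1.54 higher on ZEB2.

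The epithelial transcription and splicing regulators had medians of -1.42, -2.02, -1.31 and -1.52 on FOXQ1, SNAI1, TWIST1 and ZEB2, and 4 of 8 measured members were lower on all 4 arrays. GRHL2, an epithelial transcription factor, differed by -4.65, -4.84, -4.82 and -4.65. TRPS1, of the same list, differed by 1.02, 1.48, 2.31 and 1.48, but by 0.51, 0.9, 0.96 and 0.42, all under 2-fold, with the median of its probe sets. Of 13 measured cornified envelope and S100 genes, 7 were lower on all 4 arrays, while FLG, filaggrin, was 1.5 higher on FOXQ1. S100A8 and S100A9, partners in the calprotectin complex, differed by -3.37 and -2.66 on FOXQ1 and by -4.21 and -3.92 on SNAI1. IVL, the cornified envelope protein involucrin, differed by -3.52, -3.1, -3.36 and -2.93.

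Of 9 measured fibrillar collagen and matrix glycoprotein genes, 5 were higher on all 4 arrays, and the medians were 2.88 on FOXQ1, 3.65 on SNAI1, 4.43 on TWIST1 and 3.04 on ZEB2. SPARC, a matrix-binding glycoprotein, differed by 3.91, 3.37, 4 and 3.59. FN1, which encodes fibronectin, differed by 0.42 on FOXQ1 and by 2.53, 2.5 and 2.11 on the other arrays. VCAN, the proteoglycan versican, differed by -1.05 on FOXQ1, where it was below the floor on both arrays, and by 5.51, 6.5 and 6.64 on SNAI1, TWIST1 and ZEB2. Collagen gene COL1A2 differed by 7.28, 7.1, 4.52 and 4.56, or by 4.33, 4.62, 1.88 and 2.62 with the median of its probe sets. The collagen cross-linking enzymes had medians of 2.08, 1.96, 2.63 and 1.83, and 4 of 7 measured members were higher on all 4 arrays. LOX, lysyl oxidase, differed by 3.41, 6.5, 7.14 and 5.02.

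Of the 15 measured inflammatory cytokines and NF-kB targets, 5 were lower on all 4 arrays, and the medians were -1.3, -1.25, -0.6 and -0.81. The chemokine CXCL5 was higher on SNAI1 and TWIST1, by 1.13 and 1.14, and CXCL3 on ZEB2, by 1.11. TNFAIP3, a negative regulator of NF-kB signalling, was among the 5 genes lower on all 4 arrays, at -2.31, -3.91, -2.65 and -2.24. The targets of YAP and TAZ, coactivators of the Hippo pathway, went both ways, with 4 of 8 members higher and 3 lower on each array. CCN2, a matricellular protein, differed by 4.94, 4.89, 5.23 and 4.83, and F3, tissue factor, by -5.2, -2.23, -1.86 and -1.73. PRRX1, a mesenchymal homeobox factor, was higher on all 4 arrays, by 3.52, 5.1, 6.87 and 8.46. TWIST2 lay within 0.24 of LACZ on every array. The mesenchymal surface and cytoskeletal genes did not move as one: the medians of 6 measured members were -0.77 on FOXQ1, -0.07 on SNAI1, 0.71 on TWIST1 and 0.54 on ZEB2, and the SNAI1 value was 0.2 after quantile normalization. CALD1, the actin-binding protein caldesmon, was the 1 member higher on all 4 arrays, at 1.77, 1.03, 1.6 and 2.21, while NT5E, a surface nucleotidase, was at -3.61 on FOXQ1 and PDPN, podoplanin, at -3.04 on SNAI1.

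Markers of other cell types and lists of general functions were also examined. The medians of 5 leukocyte markers were 0, -0.27, -0.01 and -0.09, with CD2, CD14 and CSF1R below the floor on all 5 arrays. LAPTM5, a lysosomal protein of the same list, differed by 4.27, -0.51, 1.11 and -2.4, so the medians do not describe it. Those of 4 endothelial markers were 0.27, 0.07, 0.02 and 0.06, with KDR and TEK below the floor. The 8 stromal fibroblast markers, which include COL1A2 from the matrix list, had medians of 0.12, 0.2, 1.97 and 0.61, with 0.99 on TWIST1 for the median of probe sets. With only the members above the floor, the fibroblast medians were 1.07, 0.65, 4.04 and 0.83. Of the 8 members, 2 were higher and 0 lower on all 4 arrays. The 6 mitotic genes had medians of 0.17, -0.22, 0.27 and 0.29, where the SNAI1 value was 0.05 after quantile normalization. The 7 housekeeping genes had medians of -0.08, -0.5, 0.09 and 0.04, which after quantile normalization were 0.01, -0.26, 0 and -0.09.

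**Figure D2:**
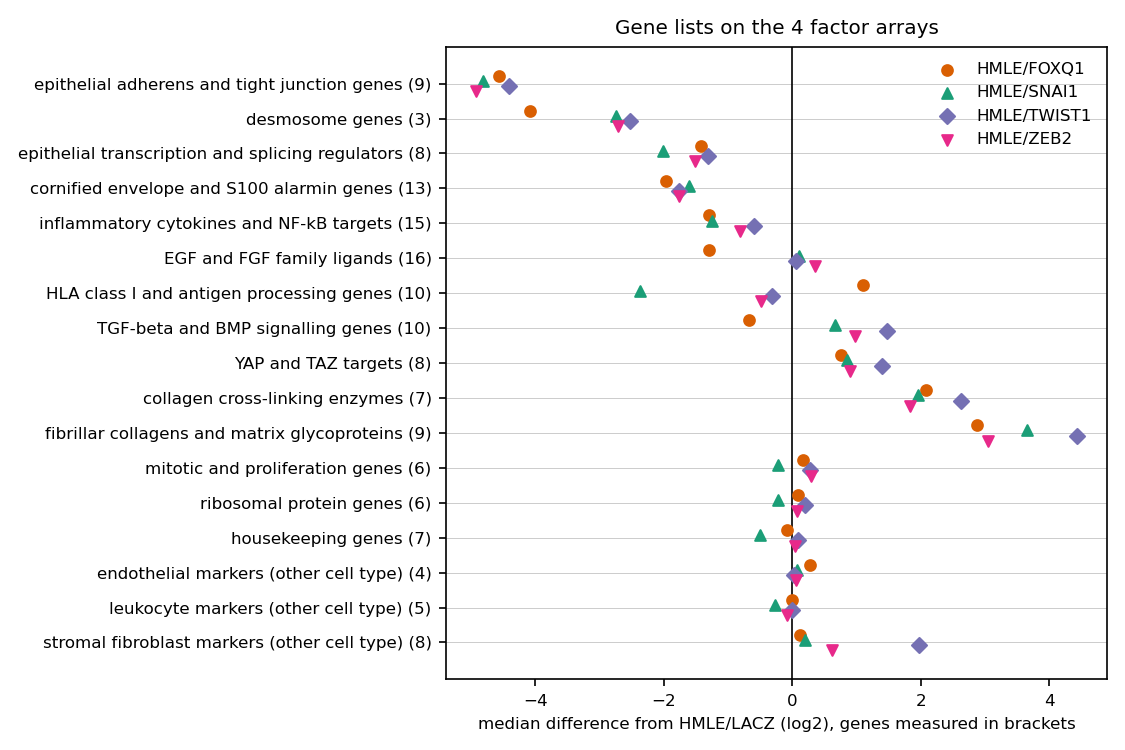
Median difference from the LACZ array (log2, horizontal axis) of 17 gene lists on the 4 factor arrays, 1 point per array, with the number of measured genes in brackets. The lists shown were picked with their values in view from 43 computed; the junction list lies between -4.92 and -4.41 and the collagen and matrix list between 2.88 and 4.43.

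FOXQ1 overexpression was compared with LACZ to describe the forkhead factor model. On the FOXQ1 array, ENPP1, an ectonucleotide pyrophosphatase, differed by 9.83, SDC2, a heparan sulfate proteoglycan, by 9.75, and MAP2, a microtubule-associated protein of neurons, by 8.45. FST, which encodes the activin antagonist follistatin, differed by -9.82, CD24, a surface glycoprotein, by -9.24, and INHBA, an activin subunit, by -8.63. In total 976 genes were 2-fold or more higher and 1041 lower. Of the 10 genes with the largest differences in each direction, NID1, RGS4, AK5, MAL2, EPCAM, S100A14, ESRP1, IL1A and RAB25 also led the shared genes. MEST, MME and IL1RL1 were among the higher genes, at 7.98, 7.83 and 7.65, and CHMP4C was among the lower, at -8.64. SDC2, MAP2, MEST, MME, FST, CD24, CHMP4C and INHBA were likewise called in the same direction on all 4 factor arrays, so they are not particular to FOXQ1.

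Growth factor ligands were lower on this array: of 16 measured EGF, FGF and related ligands, 9 were lower and 3 higher, with a median of -1.29. NRG1, neuregulin, differed by -4.15, HBEGF, a heparin-binding EGF-like ligand, by -3.97, and VEGFC, a lymphatic growth factor, by -3.76. The medians of this list were 0.1, 0.05 and 0.36 on SNAI1, TWIST1 and ZEB2, and the TWIST1 value was -0.13 after quantile normalization. Inflammatory genes were lower too, 10 of 15, with CXCL1 and CXCL8, neutrophil-attracting chemokines, at -7.65 and -5.11. The TGF-beta and BMP list had a median of -0.67, with 1 of 10 members higher and 2 lower. SNAI2, itself an EMT factor, differed by -2.33. HLA class I and antigen processing genes had a median of 1.1, with 6 of 10 members higher, among them PSMB9 at 1.99 and HLA-B at 1.79, and 1 lower, TAP2, a peptide transporter subunit, at -1.62.

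SNAI1 overexpression was compared with LACZ in the same way. The largest higher differences were those of CADM3 at 9.48, NID1 at 9.15, NREP at 8.92 and ROS1, a receptor tyrosine kinase, at 8.91. LTBP1, a binding protein of latent TGF-beta, differed by 8.01, and HHIP, an inhibitor of hedgehog signalling, by 7.78. The lower genes were led by MAL2, EPCAM and IL1B, at -12.78, -11.93 and -11.81, and included CLDN1 at -9.23 and NMU, a neuropeptide, at -8.66. There were 635 higher and 1196 lower genes, so that 34.7% were higher. After quantile normalization the numbers were 877 and 889, or 49.7% higher. That scaling gives the arrays equal distributions, so it tends to balance the split by construction. Centring on the median gene left 769 higher and 987 lower, or 43.8% higher. The median difference over all genes was -0.09 as deposited and 0.03 after quantile normalization. The size of the excess of lower genes therefore depended on the scaling.

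HLA class I and antigen processing genes, which serve to present peptides to T cells, were lower on the SNAI1 array. Of 10 measured members 8 were 2-fold or more lower and none higher, with a median of -2.37, at percentile 0 of 10000 random lists. PSMB9 and PSMB8, subunits of the immunoproteasome, differed by -5.04 and -3.42, TAP1, a peptide transporter subunit, by -2.32, and HLA-B by -1.16. The medians on TWIST1 and ZEB2 were -0.31 and -0.49. Of 5 measured targets of NRF2, the regulator of the antioxidant response, 3 were lower and 1 higher on SNAI1, with a median of -1.77. GCLC, which catalyses a step of glutathione synthesis, was at -2.68 and SLC7A11, a cystine transporter, at 1.06. The collagen gene COL6A3 differed by 6.95 on this array.

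**Figure D3:**
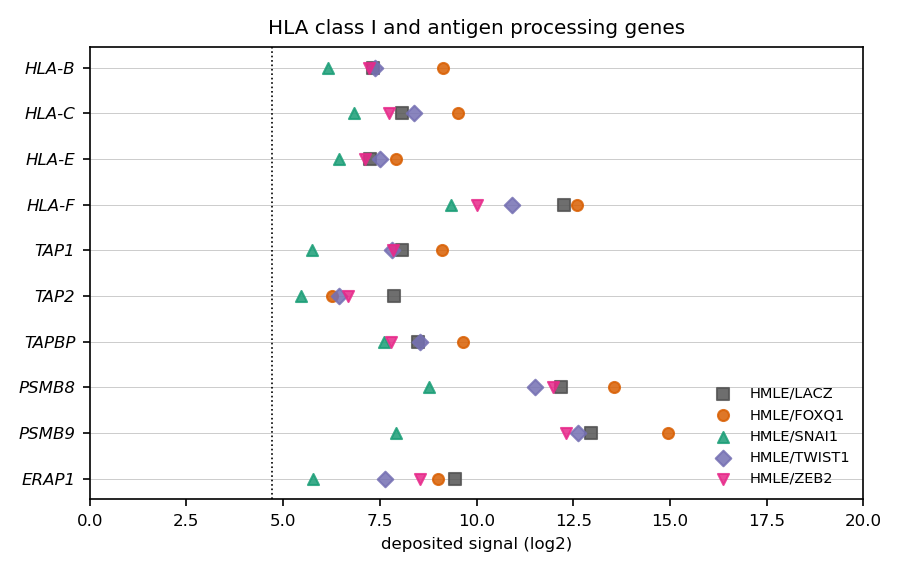
Deposited signal (log2, horizontal axis) of 10 HLA class I and antigen processing genes, 1 point per array, with the dotted line at the level floor of 4.72. PSMB9 lies at 7.93 on SNAI1, 12.97 on LACZ and 14.96 on FOXQ1.

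TWIST1 overexpression gave its largest higher differences from LACZ in NID1 at 10.43, CADM3 at 9.67, ROS1 at 9.56 and RGS4 at 9.32. PLAC8 differed by 8.53, LTBP1 by 8.37 and ENPP2, the lysophospholipase autotaxin, by 7.66, or by 4.37 with the median of the ENPP2 probe sets. MAL2, EPCAM and S100A14 led the lower genes at -13.52, -12.22 and -10.81, and FST stood at -9.17. In total 1085 genes were higher and 630 lower, or 63.3% higher. After quantile normalization 884 were higher and 783 lower, or 53% higher. Centring on the median gene gave 65.6% higher. Of the 10 measured TGF-beta and BMP genes, 7 were higher and 2 lower, with a median of 1.48. ID2 and ID3, inhibitors of helix-loop-helix factors, differed by 5.35 and 3.23, and SNAI2 by 1.2. PDGFRA, a receptor tyrosine kinase of mesenchymal cells, differed by 4.04, and DPT, the matrix protein dermatopontin, by 4.27.

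ZEB2 overexpression gave its largest higher difference in UCHL1, a deubiquitinating enzyme of neurons, which was at 4.11 on LACZ and 14.39 on ZEB2. RGS4 differed by 10.14, CADM3 by 9.99, HHIP by 8.5, PRRX1 by 8.46 and IGFBP3, an insulin-like growth factor binding protein, by 7.93. The lower genes were led by MAL2, EPCAM and ESRP1, at -13.18, -11.67 and -11.16, with CD24 at -9.5. In total 955 genes were higher and 645 lower, or 59.7% higher, against 807 and 754, or 51.7% higher, after quantile normalization. Centring on the median gene gave 60.4% higher. TGF-beta and BMP genes had a median of 0.98, with 5 of 10 higher and 2 lower. Among the growth factor ligands 7 of 16 were higher and 3 lower, with FGF2, a fibroblast growth factor, at 3.52 and EREG, the EGF receptor ligand epiregulin, at 2.62.

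The models were then compared with each other, which the series design names as an aim. The TWIST1 and ZEB2 arrays lay closest, with 740 genes 2-fold or more apart. SNAI1 differed from ZEB2 in 1141 genes and from TWIST1 in 1250, and FOXQ1 differed from TWIST1 in 1153, from ZEB2 in 1563 and from SNAI1 in 1647. FOXQ1 stood 2-fold or more above all 4 other arrays in 179 genes and below all of them in 229. APOD, a lipid-binding apolipoprotein, was at 13.65 on FOXQ1 and at most at 5.76 elsewhere, followed by GDA, CA8, IL1RL1 and EPHB6. FOXP1, a forkhead factor, was at 5.46 on FOXQ1 and at least at 11.95 elsewhere, followed by SPRY4, CXCL1, INHBA and STEAP1. The probe sets of FOXP1 differed among themselves, and their median gave -3.58 on FOXQ1 in place of -6.49.

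SNAI1 stood above all other arrays in 42 genes and below them in 185. CTHRC1, a secreted matrix protein, was at 11.76 on SNAI1 and at most at 9.5 elsewhere, and PSMB9, CAP2, TPD52, PLS1 and ITGA6 led the lower genes. ITGA6, an integrin subunit of hemidesmosomes, was at 9.92 on SNAI1 and at least at 13.27 elsewhere. TPD52 differed from LACZ by -7.13 on SNAI1, or by -3.74 with the median of its probe sets. TWIST1 stood above all others in 53 genes and below in 10, led by the long noncoding RNA PANTR1, at 10.56 against at most 4.9 elsewhere, PDGFRA and DPT. ZEB2 stood above all others in 87 genes and below in 27, led by IGFBP3 and UCHL1. QRFPR, a peptide receptor, was at 12.08 on ZEB2, 8.66 on LACZ and at most 7.19 on the other 3 factor arrays. In the simulated arrays without differences, LACZ stood below all others in at most 82 genes and above them in at most 94. No TWIST1 or ZEB2 count, nor the 42 of SNAI1, exceeded these, so noise stays open for such genes. The simulated noise was drawn from the differences between TWIST1 and ZEB2, which include the genes that set either array apart. The comparison therefore cannot decide whether the TWIST1 and ZEB2 counts reflect noise. It also does not weigh the size of single differences. With 1 array per line, a difference between models cannot be told from a difference between single cultures.

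**Figure D4:**
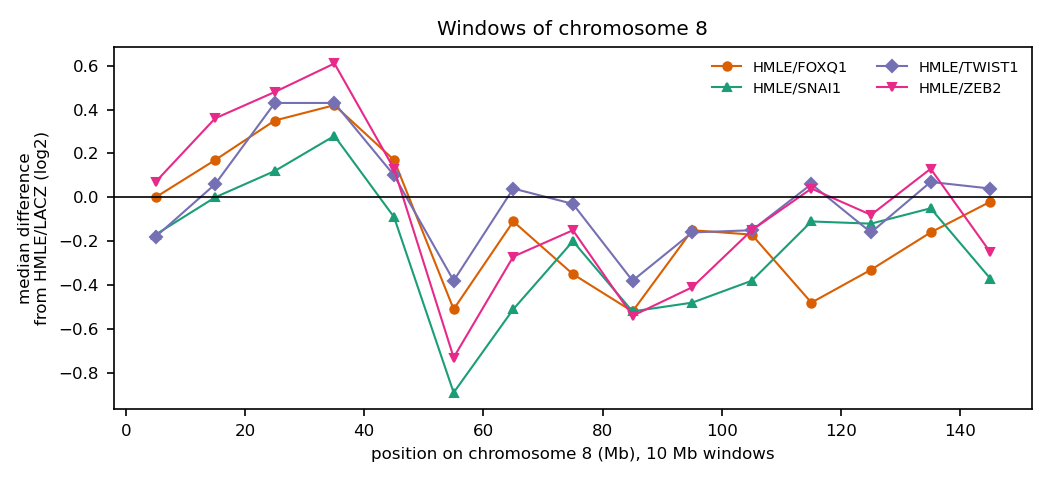
Median difference from the LACZ array (log2, vertical axis) of genes in 10 Mb windows of chromosome 8 (horizontal axis, Mb), 1 line per factor array. The window at 30 to 40 Mb lies between 0.28 and 0.61 and the window at 80 to 90 Mb between -0.54 and -0.38.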

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

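The tests of noise in the LACZ array, of dilution by other cells, of signal shared among HLA probe sets and both tests on chromosome 8 were chosen after the results were seen. The genes shared by the 4 factor arrays are weighed first because every difference used 1 LACZ array. Random noise of that array would leave gene lists near 0, but the junction list median nearest to 0 was -4.41. That list was chosen with its low medians in view, so the value speaks only for its genes. Simulated noise alone shared 64.72 higher and 74.63 lower genes, so noise stays open for part of the others. A different distribution of values on LACZ would remove shared genes under quantile normalization, which gave 681 against 665. Dilution or replacement of LACZ-like cells by cells of another kind stays open: the smallest difference of EPCAM, ESRP1 and RAB25 was -8.66, but these genes were among the most extreme of the pattern, so the test decides nothing. A shared response to the 4 factors stays a hypothesis, and selection during line making or a LACZ culture unlike its parent line may also account for it and were not tested.

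HLA class I and antigen processing genes had medians of -2.37 on SNAI1 and 1.1 on FOXQ1. Of 10 members, 5 were lower on SNAI1 and higher on FOXQ1, and TAP2 was lower on all 4 factor arrays. The difference between the SNAI1 and FOXQ1 arrays was not tested. A level-dependent shift of the SNAI1 array left the median at -2.21 after its removal. Loss of the chromosome 6 region at 26 to 34 Mb would lower its other genes, but 249 of them had a median of -0.14. A loss confined to the short stretch that holds PSMB8, TAP1 and PSMB9 would not show in that median and stays open. Signal shared among near-identical HLA probe sets would spare the 6 members outside the HLA family, which had a median of -2.92. An effect of SNAI1 stays a hypothesis, and with 1 culture per line the pattern may equally be a state of that culture.

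Neighbouring genes of chromosome 8 moved together on all 4 factor arrays, in regions picked from a scan of the same data. Among the 59 genes at or above the floor at 30 to 40 Mb and the 38 at 80 to 90 Mb, at least 72.9% lay on the region's side on each array. Shares of that size argue, for these regions, against a shift made by a few strongly regulated genes. Regions picked for their medians tend to show such shares, so the shares do not tell how unusual the regions were. If the LACZ and factor cultures differed in chromosome content, adjacent windows would move alike, and the medians of adjacent 10 Mb windows correlated with r = 0.41 over 144 pairs, above the highest of 10000 shuffled orders, 0.3. Without chromosome 8 the correlation was 0.35 over 130 pairs. A copy number difference may therefore contribute, but neighbouring genes that are regulated together would give the same correlation, and DNA was not analysed here.

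In total 104 genes were 2-fold or more higher on 1 factor array and 2-fold or more lower on another, and these differences were not tested. LAPTM5, of the leukocyte list, differed by 4.27 on FOXQ1 and by -2.4 on ZEB2. CLDN11, a claudin, differed by 3.92 on FOXQ1 and 3.79 on TWIST1 and by -2.35 on SNAI1 and -2.47 on ZEB2. Outside the named genes, 239 of 49951 probe sets were 2-fold or more higher than LACZ on all 4 factor arrays, and 363 were lower.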

How the results depend on the processing

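Counts followed the threshold and the floor, as their construction requires. At 3-fold the higher and lower genes numbered 515 and 530 on FOXQ1, 311 and 524 on SNAI1, 517 and 268 on TWIST1 and 439 and 307 on ZEB2, the shared genes 156 and 176, and the genes apart 163, 56, 12 and 33. At 1.5-fold they were 1704 and 1815, 1211 and 2240, 1909 and 1325, and 1795 and 1335, with 607 and 693 shared and 931, 746, 296 and 409 apart. With the floor at percentile 75, counts that moved over 1.5 times were 661 lower on FOXQ1, 387 higher and 765 lower on SNAI1, 335 lower on TWIST1, 626 higher and 370 lower on ZEB2, 199 shared lower, and 151, 32 and 66 apart on SNAI1, TWIST1 and ZEB2. The mean of the 4 arrays gave 760 higher and 695 lower. Without 1 factor array, shared counts ranged from 331 to 442 higher and from 355 to 400 lower. Without the SNAI1 and FOXQ1 arrays, chosen after seeing the data, 662 were higher and 417 lower.

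The size of the excess of lower genes on SNAI1 depended on the scaling. After level-dependent normalization, added after seeing the data, 48.4% of its calls were higher, against 34.7%. Centring on the median gene gave 43.8%. The test of such a shift as the cause was written before its result, withdrawn once the result was seen and then restored. It decides nothing, since centring at each level moves the split toward balance by construction, as quantile normalization also tends to do. Of the shared genes, 303 higher and 320 lower were kept under quantile normalization, and 315 and 321 under level-dependent normalization. None of 832 single-gene differences moved over 1.5-fold under quantile, centring or level-dependent scaling, and 42 did with the median of probe sets. Of the list medians, 5 of 172 moved with that median and 10 of 156 with only members above the floor. None of the called differences among these 832, and no list median of at least 1 in size, reversed. The limit of 1.5-fold compared processings of the same arrays and does not measure the missing replicate error. No paired analysis was possible because each line had 1 array. Values near background do not give the exact size of a difference.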

Other observations

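TERT (chromosome 5, 1253167 to 1295068), the catalytic subunit of telomerase, was higher on all 4 factor arrays, at 11.67 on FOXQ1, 13.31 on SNAI1, 11.7 on TWIST1 and 12.89 on ZEB2 against 8.16 on LACZ. With the median of its probe sets the differences were 1.63, 2.34, 1.4 and 2.19. HMLE cells were made with an introduced TERT gene, and whether the probes read that copy was not known here.

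Cholesterol synthesis genes had a median of 0.95 on FOXQ1, where 3 of 6 measured members were higher, with INSIG1, a regulator of sterol sensing, at 2.61 and FDPS, a synthase of the mevalonate pathway, at 1.56. Their medians were -0.12, 0.25 and 0.5 on SNAI1, TWIST1 and ZEB2, which after quantile normalization were 0.11, -0.01 and 0.33. Cell cycle inhibitors and p53 targets had a median of -0.99 on SNAI1, where 4 of 8 were lower and 1 higher, with CDKN1A, the inhibitor p21, at -1.94, SFN, the epithelial 14-3-3 protein sigma, at -4.91 and TP53I3, a p53-induced oxidoreductase, at 1.26. SFN was also lower on FOXQ1, TWIST1 and ZEB2, at -3.95, -3.11 and -2.71. Of 6 measured hypoxia and glycolysis genes, 3 were lower on each array and SLC2A1, a glucose transporter, was 1.47 higher on TWIST1, while NDRG1, a stress-responsive gene, was at -3.01, -2.85, -1.54 and -3.2.

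CD24 was lower and MME, a surface peptidase of myoepithelial cells, higher on all 4 arrays, at -9.24 and 7.83 on FOXQ1, -6.35 and 2.38 on SNAI1, -5.1 and 6.11 on TWIST1 and -9.5 and 3.18 on ZEB2. Windows along chromosomes 1 to 9 stood beyond the central 99% of random gene sets in 17 of 158 cases, against 1.6 by chance. Besides chromosome 8 they included windows of chromosome 3 at 40 to 60 Mb, which were higher on FOXQ1, TWIST1 and ZEB2. The windows were ranked on the mean difference of the 4 factor arrays, so shifts that differ in direction between factor arrays may not show.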
